A study of Arabidopsis thaliana with 15 samples.

How the data were processed

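Chromatin from dissected inflorescence meristems of Arabidopsis thaliana plants grown in long days was immunoprecipitated with an anti-GFP antibody (ab290) and sequenced. There were 15 samples: 3 GFP-MYB3R1, 3 GFP-MYB3R4 and 2 GFP-MYB3R4mNES ChIP libraries, and 3, 2 and 2 input samples of the same lines. Per the labels, part of the libraries were prepared in-house and part by a company with another method, and 2 sequencing set-ups were used, without saying for which samples. The files follow 2 styles of name (MYB3R1 and MYB3R4 replicates 1 and 2; all others), which were taken as a possible library batch. The samples include no ChIP from untagged plants. The labels do not say whether replicates came from separate plants, so p-values across libraries measure only the spread between these samples.

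For each ChIP library the deposited file was a list of peaks in narrowPeak format, called by the authors relative to input with reads extended to 400 bp, as the file names state. FastQC, Trimmomatic, Bowtie2 and Picard and the build TAIR10 are named in the submitters' processing notes, without versions, and the peak caller is not given in the sources used here. Per the labels of the format and a check of the values, the deposited columns held a whole-number score that is 10 times the -log10 q-value, the fold enrichment at the summit (a ratio over the background from input), the -log10 p-value and the -log10 q-value of the peak, and another column with the summit's distance in bp from the peak start. The lowest -log10 q-value of a list lay between 1.31 and 2.09, so that all peaks passed q = 0.05 (1.30 on this scale). Fold enrichment and p-values were used to rank peaks within a list; fold enrichments are also printed for each library as deposited, and no test compares them between lists. Which input sample was used for which ChIP library is not stated, and 2 input samples stand against 3 MYB3R4 libraries. Files of the input samples were not analysed here. No read counts were at hand, so depth is unknown, and no interval or detection limit was given. A gene without a peak is therefore one not called at the depth of that library. No rows of a list shared start and end.

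Peaks on the mitochondrial and plastid genomes were counted and left out of all else. Genes came from a reference table of the assembly TAIR10.1 with 27444 nuclear protein-coding genes and no strand. The window planned for gene starts (1000 bp upstream to 200 bp downstream) was therefore applied at both ends of each gene, from 1000 bp outside to 200 bp inside, and a gene was called bound when a peak summit lay there. A summit between neighbouring genes counts for both, and the 3' end counts as well as the 5' end. Whether peaks and genes shared a coordinate system was checked by shifting the genes by 2000 to 20000 bp: 21.5% to 54.1% of summits lay within 500 bp outside a gene end in place and 10.6% to 25.5% after shifting. A target was a gene bound in at least 2 libraries of a group. The 10 lists of known genes, written from memory with 328 identifiers, all 328 of which were found in the table, and a list of ribosomal protein genes by symbol made 11. The symbol rule also took 4 disease resistance genes (such as RPS2, AT4G26090); without them 31 of 40 genes were MYB3R1 targets (odds ratio 4.26, adjusted p = 1.63e-04 by Fisher's exact test). Symbols are those of the table.

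Named genes were chosen by a rule: the genes of MYB3R1 and MYB3R4, up to 4 members of each list bound in the most libraries (12 for G2/M genes, and up to 4 bound in none), the 8 strongest targets of each group by median percentile of fold enrichment, and up to 5 genes bound in all libraries of one group and none of the other. The lists, this rule, the windows, tests and most alternatives were fixed before the data were examined. The text names part of the genes so chosen. Counts and shares per library were compared by exact permutation tests of the difference of means, two-sided, which cannot go below 0.10 for 3 libraries against 3 or below 0.20 for 3 against 2 as run here. List enrichment used Fisher's exact test, two-sided, against all other nuclear protein-coding genes, with Benjamini-Hochberg adjustment over 33 tests (11 lists, 3 groups) and a threshold of 0.05. Target overlaps used the same test unadjusted. Where a cell of the table was empty, a constant was added to every cell for the odds ratio only (Haldane correction). Genes are not independent replicates in these tests. Peak overlap meant 1 bp or more, with 100 random placements of the same peaks on their chromosomes for comparison.

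Alternatives were a -log10 q of at least 5 or 10, the same number of peaks from each library (the 227 strongest by -log10 p), windows of 500 and 2000 bp, any part of the peak in the window, targets bound in every library or in at least 1, a background of genes bound in at least 1 library, a reciprocal overlap of 50%, each library left out, libraries of 1 naming style only, and the replicate number as a block. Chosen after seeing the data were the nearest gene end only, lists without dense windows (10 windows of 100 kb with 10 or more summits in any of the 4 shortest lists, all of MYB3R4 or MYB3R4mNES, so that leaving them out removes places with peaks of these forms by construction), equal lengths and no dense windows together (141 peaks), and the ribosomal list without resistance genes. Motif searches, planned for the mitosis-specific activator element, were not run since no genome sequence was used here. The procedure was tested on simulated data: with 20 draws of random peaks 0 of 660 list tests were called, 100% of 200 planted genes were called with 1.58 genes per planted gene because neighbours share windows, and G2/M enrichment was called in 40 of 40 tests with 15 planted members. Random peaks were placed evenly and independently for each library, unlike the real lists, which overlap between replicates. The same 15 members were planted in every library of a draw. These draws therefore check the procedure and do not tell how often real lists give false calls. The result for 1 gene family is not reported here. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.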

Results

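Binding of 2 MYB transcription factors with 3 MYB repeats, MYB3R1 and MYB3R4, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against GFP in dissected inflorescence meristems of Arabidopsis thaliana. The plants, of the Col0 background, carried GFP-MYB3R1, GFP-MYB3R4 or GFP-MYB3R4mNES, a form whose suffix the labels do not spell out (NES is the usual abbreviation for a nuclear export signal). There were 3 ChIP libraries for MYB3R1, 3 for MYB3R4 and 2 for MYB3R4mNES, besides 7 input samples. Each ChIP library had 1 list of peaks called relative to input. Read depth was unknown, so list length and fold enrichment were the measures of how much each library showed. Median fold enrichments were 3.04, 2.76 and 2.21 in MYB3R1 replicates 1, 2 and 3, and 1.74, 2.04 and 1.94 in those of MYB3R4. In MYB3R4mNES replicates 1 and 2 they were 1.98 and 2.53. The lists held 11478, 19655 and 7089 nuclear peaks for MYB3R1 replicates 1, 2 and 3. They held 786, 2717 and 456 for MYB3R4 replicates 1, 2 and 3, and 227 and 256 for MYB3R4mNES replicates 1 and 2.

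**Figure D1:**
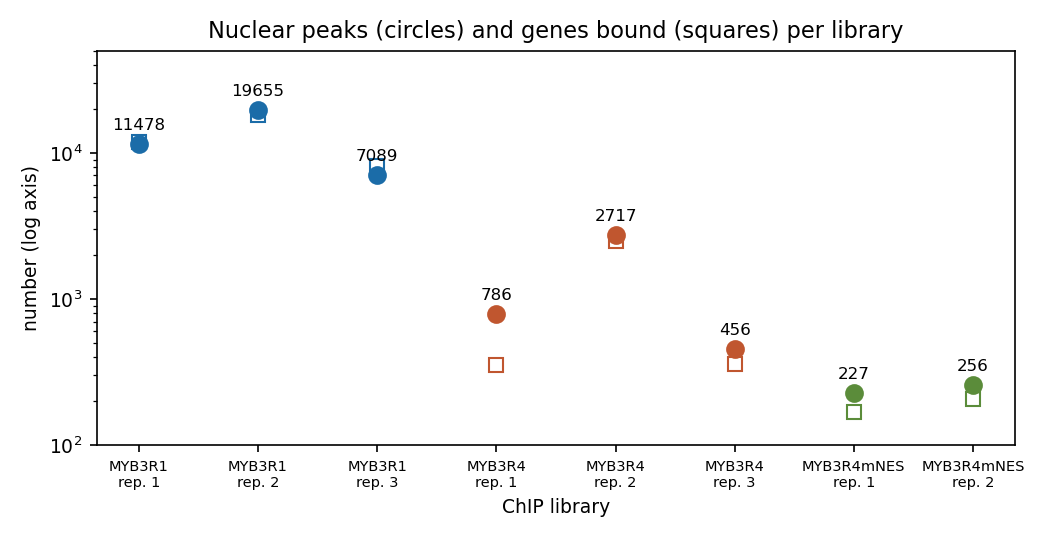
Number of nuclear peaks (circles, with their values) and of protein-coding genes bound (squares) in each of the 8 ChIP libraries, on a log axis, coloured by group. The 3 MYB3R1 libraries lie between 7089 and 19655 peaks and the 5 others between 227 and 2717.

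The comparison of MYB3R1 with MYB3R4 asked which genes each protein bound in the meristem. Both proteins bound genes of mitosis and cytokinesis, and MYB3R1 bound nearly all of them. Of 58 listed G2/M genes, the MYB3R1 libraries bound 93.1% ± 1.72 (SD, n = 3) and the MYB3R4 libraries 28.7% ± 9.80 (SD, n = 3). Genes of DNA replication and histone genes were bound in MYB3R1 libraries at 90.9% ± 6.06 and 85.5% ± 10.0 (SD, n = 3) of their lists. In MYB3R4 libraries the same lists were bound at 4.04% ± 7.0 and 2.90% ± 5.02 (SD, n = 3), and only replicate 2 bound any member. Highly transcribed reference genes were bound at 90.2% ± 3.40 in MYB3R1 and 13.7% ± 13.6 in MYB3R4 libraries (SD, n = 3 each). This list was named without expression data, so how highly each member is transcribed was not measured. Without ChIP from untagged plants, binding by MYB3R1 was not told apart from signal common to highly transcribed genes. Of all genes, MYB3R1 libraries bound 46.3% ± 18.3 and MYB3R4 libraries 3.90% ± 4.52 (SD, n = 3 each; 1.29%, 9.12% and 1.3% in replicates 1, 2 and 3). Every MYB3R1 library lay above every MYB3R4 library for the G2/M list, by 64.4 percentage points between the means (exact permutation test, two-sided, p = 0.10). With 3 libraries against 3, 0.10 is the smallest p this test can give. With the lists brought to an equal length of 227 peaks, the strongest in each library, the G2/M shares were 56.3% ± 0.995 and 19.5% ± 2.63 (SD, n = 3 each), a difference of 36.8 percentage points (exact permutation p = 0.10). With 141 peaks per library, after 10 windows of 100 kb crowded with peaks in MYB3R4 or MYB3R4mNES lists were left out, the difference in percent of G2/M list bound, MYB3R1 against MYB3R4, was 26.4 points (exact permutation p = 0.10). With 227 peaks S-phase genes were bound at 15.2% ± 6.06 (SD, n = 3) in MYB3R1 and 0% in MYB3R4 libraries, and histone genes at 0% in both. The reference genes were then bound at 5.88% in both.

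**Figure D2:**
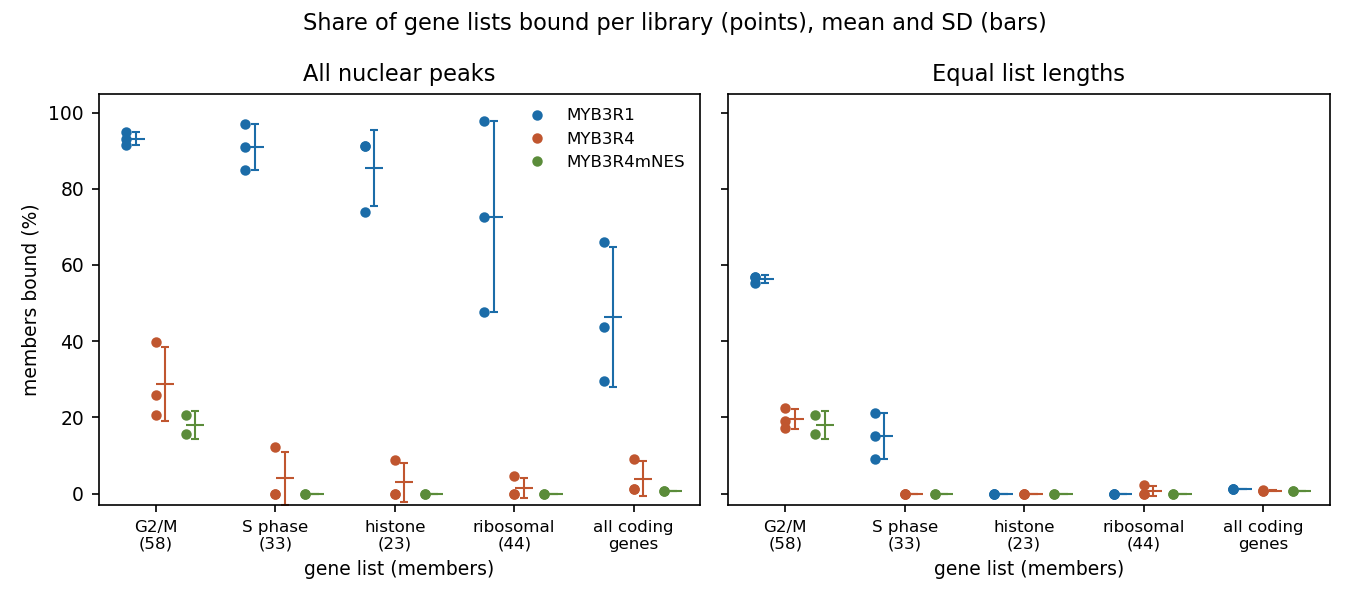
Percent of the members of 4 gene lists, and of all protein-coding genes, bound in each library (points), with the mean and SD of each group (bars), from all nuclear peaks (left) and from the 227 strongest peaks of each library (right). In both panels every MYB3R1 library lies above every other library for the G2/M list, and with equal list lengths no library bound a listed histone gene.

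A gene bound in at least 2 libraries of a group was counted as a target. MYB3R1 had 12283 targets, which is 44.8% of 27444 nuclear protein-coding genes, and MYB3R4 had 385, which is 1.40%. Among MYB3R1 targets were 55 of the 58 G2/M genes (odds ratio 22.7, adjusted p = 5.29e-15 by Fisher's exact test). Among MYB3R4 targets were 16 of the 58 (odds ratio 27.9, adjusted exact p = 2.55e-15). For MYB3R1, 6 other lists of the 11 were also enriched. S-phase genes had 30 of 33 members among the targets (odds ratio 12.4, adjusted exact p = 2.96e-07), and replication-dependent histone genes 20 of 23 (odds ratio 8.24, adjusted exact p = 2.38e-04). Genes of the MYB3R, E2F and DREAM group, regulators of cell cycle transcription, had 18 of 20 (odds ratio 11.1, adjusted exact p = 1.87e-04). The remaining enriched lists were photosynthesis genes with 28 of 34 (odds ratio 5.77, adjusted exact p = 9.02e-05), highly transcribed reference genes with 16 of 17 (odds ratio 19.8, adjusted exact p = 1.40e-04) and ribosomal protein genes with 32 of 44 (odds ratio 3.30, adjusted exact p = 7.65e-04). MYB3R4 targets held 1 cytokinin gene, 2 shoot meristem and flower regulators, 1 of the G1 cyclins and CDK inhibitors and 1 reference gene, and none of the other 6 lists' members. None of these passed the test. With 227 peaks per library, MYB3R1 had 319 targets and 3 enriched lists: G2/M genes with 33 of 58 (odds ratio 125, adjusted exact p = 1.17e-47), S-phase genes with 5 of 33 (odds ratio 15.4, adjusted exact p = 3.08e-04), and G1 cyclins and CDK inhibitors with 4 of 27 (odds ratio 15, adjusted exact p = 0.00168). With the 10 crowded windows left out and the lists cut to 141 peaks, S-phase genes had 2 of 33 and were no longer called (adjusted exact p = 0.125), whereas with only those windows left out they had 29 of 33 (odds ratio 8.97, adjusted exact p = 3.29e-06). Against only the genes bound in at least 1 library, calls ended for replication-dependent histone genes among targets of MYB3R1 (adjusted exact p = 0.185), MYB3R, E2F and DREAM complex genes among targets of MYB3R1 (adjusted exact p = 0.144), highly transcribed reference genes among targets of MYB3R1 (adjusted exact p = 0.0978) and ribosomal protein genes among targets of MYB3R1 (adjusted exact p = 0.791). Of the 18623 genes of this background, 18465 were bound in a MYB3R1 library. It therefore sets MYB3R1 targets mostly against genes bound in 1 MYB3R1 library, which lowers the contrast by construction.

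The G2/M genes bound in all 8 libraries were SYP111 (AT1G08560, the cytokinesis syntaxin also called KNOLLE), TPX2 (AT1G03780, a spindle protein), CDC20.1 (AT4G33270) and CDC20.2 (AT4G33260), activators of the anaphase-promoting complex, the B-type cyclins CYC1BAT (AT5G06150), CYCB2;4 (AT1G76310) and CYCB2;2 (AT4G35620), CSLD5 (AT1G02730), which makes cell wall polysaccharide, and PLE (AT5G51600), a microtubule-bundling protein of the phragmoplast. The TPX2 peak of MYB3R1 replicate 1 spanned positions 951352 to 952350 on chromosome 1 (TAIR10) with a summit fold enrichment of 26.1, the highest in that list. Its fold enrichment was 12.6 and 15.2 in MYB3R1 replicates 2 and 3, 3.45, 4.26 and 5.07 in the MYB3R4 replicates, and 3.15 and 4.73 in the MYB3R4mNES replicates. The SYP111 peak had its summit at position 2710987 of chromosome 1 in MYB3R1 replicate 1, with fold enrichments of 15.9, 11.4 and 8.84 in the MYB3R1, 4.63, 6.22 and 6.77 in the MYB3R4 and 4.45 and 5.77 in the MYB3R4mNES replicates. CDC20.1 and CDC20.2 are neighbours. In MYB3R4 and MYB3R4mNES libraries the highest-fold peak of both was that at CDC20.2 (summit at position 16043506 of chromosome 4 in MYB3R4 replicate 1). In MYB3R1 libraries CDC20.1 had a highest-fold summit of its own (position 16046887 in replicate 1, fold enrichment 18.9). A separate summit at CDC20.1 was not confined to MYB3R1. In every setting that kept all libraries, CDC20.2 was bound in 8 libraries and CDC20.1 in 7 or 8. These settings include the nearest gene end, where each summit counts for 1 gene. CYC1BAT shares its peak with the neighbouring ATO (AT5G06160). Of the 58 genes, 28 were bound in all 3 MYB3R1 libraries and in no library of the other groups. CYCA2;3 (AT1G15570), AUR2 (AT2G25880) and FZR3 (AT5G13840) were bound in none of the 8. With any part of the peak counted, CYCA2;3 and FZR3 were bound in 3 libraries each, and with a window of 2000 bp CYCA2;3 was bound in 4, while AUR2 stayed at 0 in every setting.

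**Figure D3:**
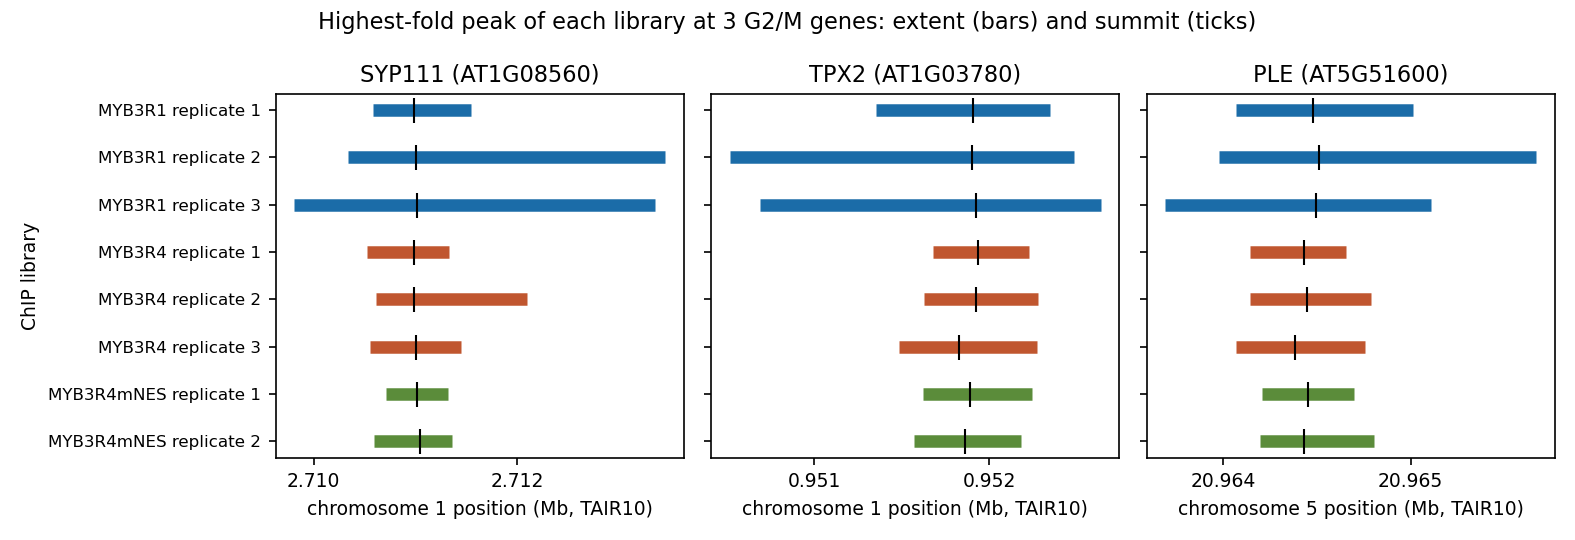
Extent (bars) and summit (ticks) of the peak with the highest fold enrichment at SYP111, TPX2 and PLE in each of the 8 libraries, against TAIR10 position in Mb, coloured by group. All 8 libraries have a peak at each gene, and the summits lie close together.

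S-phase genes bound in the most libraries were ICU2 (AT5G67100, a DNA polymerase alpha subunit), MET1 (AT5G49160, the maintenance DNA methyltransferase), ORC3 (AT5G16690, of the origin recognition complex) and MCM10 (AT2G20980, a replication factor), each in 3 MYB3R1 libraries and 1 MYB3R4 library. At ICU2 the summit fold enrichments were 7.75, 7.50 and 4.79 in the MYB3R1 replicates. The MYB3R4 peak, in replicate 2 with a fold enrichment of 2.01, lay at the other end of the gene. The histone gene HTA10 (AT1G51060, a histone H2A) was bound in the 3 MYB3R1 libraries with fold enrichments of 6.89, 7.09 and 4.22, and in no other. Among the G1 cyclins and CDK inhibitors, AT5G40460 was bound in all 8 libraries. Its fold enrichment was 24.9, 12.2 and 18.4 in the MYB3R1, 2.76, 3.29 and 3.12 in the MYB3R4, and 2.76 and 3.39 in the MYB3R4mNES replicates. CYCD4;1 (AT5G65420, a D-type cyclin) was bound in the 3 MYB3R1 libraries (fold enrichments 14.2, 10.6 and 8.17) and in MYB3R4 replicate 2 (2.29). MYB3R1 targets held 17 of the 27 genes of this list, 26 of 46 cytokinin genes, 25 of 51 shoot meristem and flower regulators and 11 of 19 nuclear transport genes, with adjusted p of 0.263, 0.377, 1.00 and 0.570 by Fisher's exact test. CRF2 (AT4G23750), a cytokinin response factor, was bound in 3 MYB3R1, 1 MYB3R4 and 1 MYB3R4mNES library. The nuclear import receptor gene IMPA-6 (AT1G02690) had fold enrichments of 12.3, 10.1 and 7.39 in the MYB3R1 replicates and 1.73 in MYB3R4 replicate 2, and was not bound in the other 4 libraries.

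At the genes of the proteins themselves, the MYB3R4 gene (MYB3R-4, AT5G11510) was bound in the 3 MYB3R1 libraries with fold enrichments of 7.33, 7.25 and 5.09, and in MYB3R4 replicate 1 with 1.24. The MYB3R1 gene (PC-MYB1, AT4G32730) was bound in MYB3R1 replicates 1 and 2 (fold enrichments 2.68 and 1.37), in MYB3R4 replicate 1 (2.22) and in MYB3R4mNES replicate 1 (2.13), at positions that differed between the groups. The strongest target peaks of MYB3R1 besides TPX2, CYC1BAT and AT5G40460 were at SAC9 (AT3G59770, a phosphoinositide phosphatase), at AT1G63100, and between MYB80 (AT5G56110) and AT5G56120. The strongest of MYB3R4 lay between GCH (AT5G64300) and AGP1 (AT5G64310, an arabinogalactan protein), at SAC9, between hemf2 (AT4G03205) and XTH9 (AT4G03210, a xyloglucan-modifying enzyme), between AT1G64760 and PnsB2 (AT1G64770), and at UBC35 (AT1G78870). The peak between GCH and AGP1 had fold enrichments of 5.90, 6.71 and 6.97 in the MYB3R4 and 24.4, 10.7 and 13.9 in the MYB3R1 replicates. UBQ10 (AT4G05320), a polyubiquitin gene of the reference list, was bound in 7 of the 8 libraries.

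MYB3R4 targets were largely MYB3R1 targets as well. The 2 lists shared 326 genes, 84.7% of the MYB3R4 targets, where 172 would be shared by independent lists (odds ratio 6.98, p = 5.52e-60, Fisher's exact test; 2.90 to 544 over the settings that keep all libraries). With 227 peaks per library they shared 129 genes, 71.3% of the MYB3R4 targets (odds ratio 353), and 66.4% with 141 peaks and the crowded windows left out (odds ratio 544). With only the crowded windows left out, 324 of 326 MYB3R4 targets were shared, or 99.4% (odds ratio 205). Of the 59 MYB3R4 targets that were not MYB3R1 targets, 57 lay in these windows, which were picked from MYB3R4 and MYB3R4mNES lists. In the other direction, 5813 genes were bound in all 3 MYB3R1 and in no MYB3R4 library. Those with the strongest peaks were AT5G55520, AT2G25890, PSAT1 (AT1G04010) and BARD1 (AT1G04020), which share a peak, and AT1G04830. The peak at AT5G55520 had fold enrichments of 15.1, 10.4 and 7.88. Only AT2G07643 and AT2G07644 were bound in all 3 MYB3R4 and in no MYB3R1 library, with peaks between 1.34 and 1.64 fold, and both lie in the crowded stretch of chromosome 2 from 3.2 to 3.7 Mb. With 227 peaks per library, 125 genes were bound in the 3 MYB3R1 libraries but no MYB3R4 library, and 12 in the 3 MYB3R4 libraries but no MYB3R1 library.

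MYB3R1 peaks also lay more often near gene ends, with 81.4% ± 0.958 (SD, n = 3) of summits within the window used to assign genes, against 56.7% ± 19.4 (SD, n = 3) for MYB3R4 (difference 24.7 percentage points, exact permutation p = 0.10; 14 points without MYB3R4 replicate 1). At random positions the share was 42.3%, 42.3% and 42.0% for MYB3R1 replicates 1, 2 and 3. MYB3R4 replicates 1, 2 and 3 had 35.4%, 73.1% and 61.6%, against 41.6%, 41.9% and 41.9% at random positions. Replicate 1 of MYB3R4 thus lay below its random share, and 228 of its 786 nuclear peaks were in the crowded windows. The MYB3R1 lists held 12741 ± 6377 nuclear peaks and the MYB3R4 lists 1320 ± 1221 (SD, n = 3 each). The difference in number of peaks, MYB3R1 against MYB3R4, was 11421 (exact permutation p = 0.10), and 7964 to 14247 with a library left out. The deposited files have 2 styles of name, which cut across both groups. Within the first style, MYB3R1 replicates 1 and 2 bound 53 and 55 G2/M genes and MYB3R4 replicates 1 and 2 bound 12 and 23. Within the other, MYB3R1 replicate 3 bound 54 and MYB3R4 replicate 3 bound 15.

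The comparison of MYB3R4 with MYB3R4mNES asked whether the mNES form bound the same genes. The MYB3R4mNES libraries bound G2/M genes as well, 18.1% ± 3.66 of the list (SD, n = 2) against 28.7% ± 9.80 for MYB3R4 (SD, n = 3), a difference of 10.6 percentage points (exact permutation test, two-sided, p = 0.40, smallest possible 0.20). Without MYB3R4 replicate 2 the difference in percent of G2/M list bound, MYB3R4 against MYB3R4mNES, was 5.17 points. The lowest MYB3R4 library and the highest MYB3R4mNES library both bound 20.7%. With 227 peaks per library the shares were 18.1% ± 3.66 and 19.5% ± 2.63, a difference of 1.44 points (exact permutation p = 0.80). MYB3R4mNES had 119 targets, 9 of them G2/M genes (odds ratio 45.5, adjusted p = 3.90e-11 by Fisher's exact test). These were the 9 genes bound in all 8 libraries, from SYP111 to PLE. AT5G40460 of the G1 cyclins and CDK inhibitors was its only other listed target.

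Most MYB3R4mNES targets were MYB3R4 targets. The targets of the 2 forms shared 113 genes, 95.0% of those of MYB3R4mNES (86.3% with 227 peaks per library), against 1.67 for independent lists (odds ratio 1873, p = 1.86e-208, Fisher's exact test). No gene was bound in both MYB3R4mNES libraries and in no MYB3R4 library, whereas 39 were bound in the 3 MYB3R4 and in no MYB3R4mNES library. One of these was HIK (AT1G18370), a kinesin of cytokinesis, with fold enrichments of 1.91, 3.27 and 2.31 in the MYB3R4 replicates. The MYB3R4mNES lists were fewer and shorter, with 227 and 256 nuclear peaks against 786, 2717 and 456. That alone favours the larger count, and no count at equal length was made for these 2 forms. The checkpoint genes MAD2 (AT3G25980) and BUBR1 (AT2G33560) were bound in 1 MYB3R4mNES library each. The strongest MYB3R4mNES peaks lay between AT1G64760 and PnsB2 (fold enrichments 5.70 and 6.37), between hemf2 and XTH9, between GCH and AGP1 (4.62 and 7.16), at SAC9, and at OLEO1 (AT4G25140, an oleosin of seed oil bodies; 4.35 and 16.7), where reads from a copy of this promoter in a transgene, if there was one, were not separated. Given only to the nearest gene end, OLEO1 was bound in 0 libraries, and with a window of 500 bp in 2. MYB3R4 lists held 1320 ± 1221 (SD, n = 3) nuclear peaks and MYB3R4mNES lists 242 ± 20.5 (SD, n = 2; exact permutation p = 0.20); without MYB3R4 replicate 2 the difference in number of peaks, MYB3R4 against MYB3R4mNES, was 380 instead of 1078. Shares of summits in the gene windows were 56.7% ± 19.4 and 56.6% ± 3.39 (exact permutation p = 1.00), and 66.7% ± 9.24 and 55.5% ± 1.87 with 227 peaks per library (exact permutation p = 0.20). Both MYB3R4mNES files share 1 naming style with MYB3R4 replicate 3, which had 456 peaks and 15 G2/M genes bound, so that within this style 1 library stood against 2, and the peak names inside the list labelled MYB3R4mNES replicate 1 carry the short name of MYB3R4 replicate 3.

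MYB3R1 and MYB3R4mNES shared 111 targets, 93.3% of those of MYB3R4mNES (76.1% with 227 peaks per library), where 53.3 would be shared by independent lists (odds ratio 17.3, p = 1.01e-29, Fisher's exact test). With only the crowded windows left out, all 109 MYB3R4mNES targets were MYB3R1 targets (odds ratio 273 with the correction for an empty cell). The 8 libraries had 103 genes in common. Replicate libraries overlapped in their peaks to different degrees. With all peaks, the replicate overlap, MYB3R4, was 45.6% on average over pairs, 25.1% with a reciprocal overlap of 50% and 29.7% without replicate 3. With all peaks, 75.8% of those of MYB3R4mNES replicate 1 and 64.5% of those of replicate 2 overlapped the other list, against 0.436% and 0.324% for the same peaks at random positions. With 227 peaks per library, 79.3% to 88.5% of the peaks of a MYB3R1 library overlapped a peak of another MYB3R1 library, 56.4% to 75.8% did so among MYB3R4 libraries, and 70.0% to 73.1% between the MYB3R4mNES libraries. Between MYB3R1 and MYB3R4 libraries the same measure was 31.7% to 41.9%, and 65.2% to 71.8% of MYB3R4mNES peaks overlapped a peak of a MYB3R4 library, as did 48.5% to 77.1% of MYB3R4 peaks with a MYB3R4mNES library. With all peaks, the lower values within groups belonged to the longer list of a pair, as for the 9.42% of MYB3R4 replicate 2 peaks found in replicate 3, against 0.528% for random positions.

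**Figure D4:**
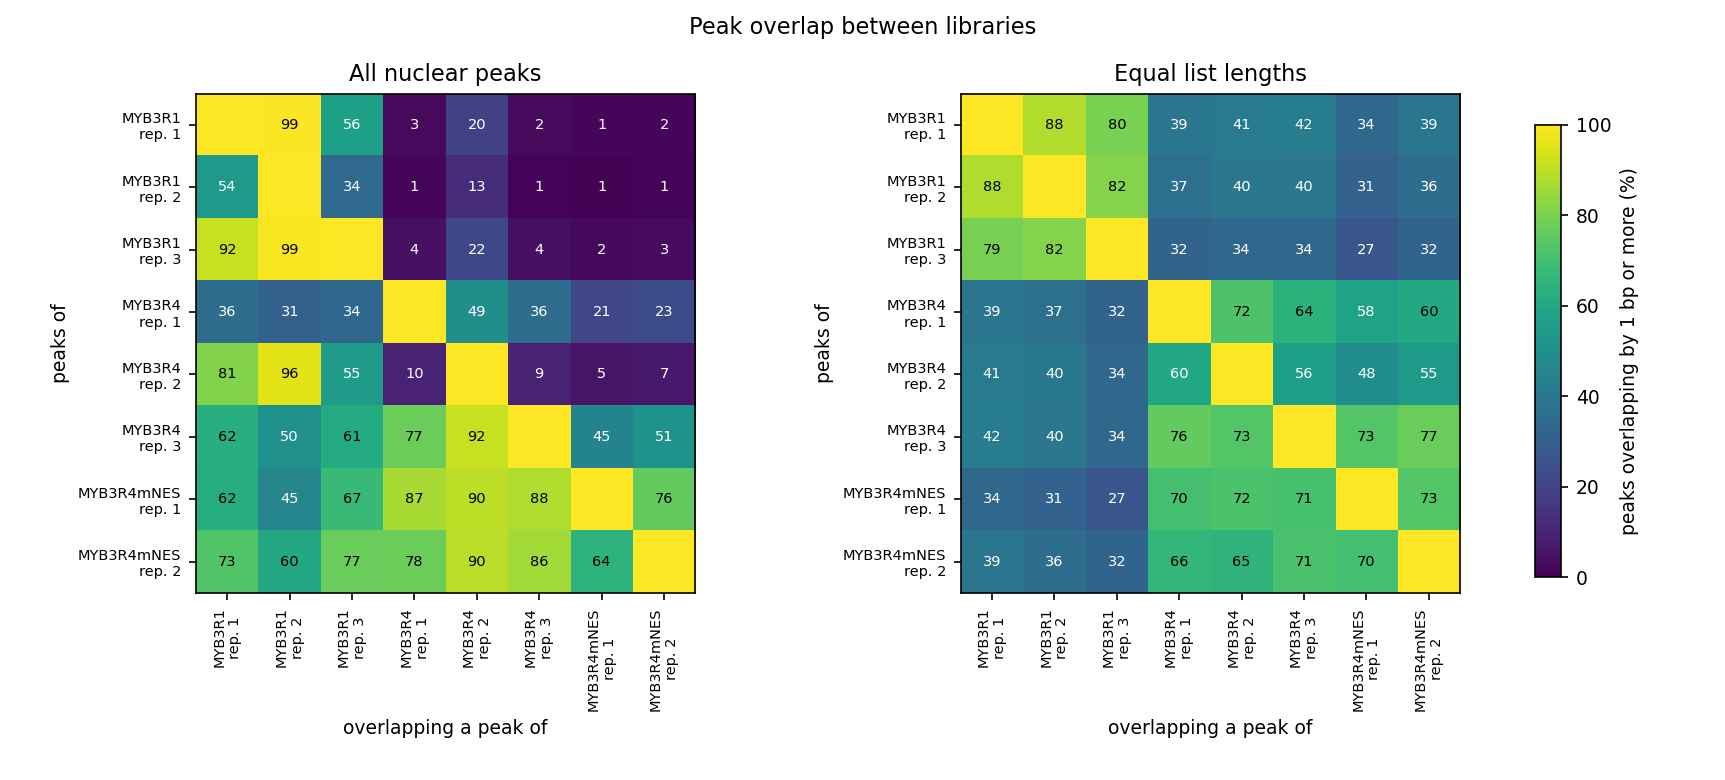
Percent of the peaks of each library (vertical axis) that overlap a peak of each other library (horizontal axis) by 1 bp or more, from all nuclear peaks (left) and from the 227 strongest peaks per library (right). At equal length, MYB3R1 libraries overlap each other at 79.3% to 88.5%, and MYB3R1 libraries overlap MYB3R4 libraries at 31.7% to 41.9%.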

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

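The tests of list length, of mitochondrial reads and of the peak names were chosen only after the result was seen. Data outside the comparisons held a signal as well: peaks on the mitochondrial genome, left out of all comparisons, numbered 71 and 36 in MYB3R1 replicates 1 and 3, 120, 20 and 166 in MYB3R4 replicates 1, 2 and 3, and 78 and 79 in MYB3R4mNES replicates 1 and 2. MYB3R1 replicate 2 had 0.

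MYB3R1 libraries bound more of the G2/M and S-phase genes than MYB3R4 libraries did. List length alone is argued against for the G2/M genes, since with 227 peaks from each library the lowest MYB3R1 library still exceeded the highest MYB3R4 library by 32.8 percentage points of the list, and with 141 peaks and no dense windows the lowest MYB3R1 and the highest MYB3R4 library stood at 41.4% and 20.7%. Weaker enrichment in the MYB3R4 libraries stays open for the S-phase genes: among the strongest MYB3R1 peaks, taken down to the 11 G2/M genes that the median MYB3R4 library holds, there were 1, 0 and 2 S-phase genes in 60, 63 and 56 peaks, so that 1 of the 3 MYB3R1 libraries would also have shown none. For the G2/M genes weaker enrichment was not tested directly and stays open as well. The G2/M genes that were MYB3R4 targets had the stronger MYB3R1 peaks (median percentile 99.5, against 96.5 for the others bound by MYB3R1). Weaker enrichment of the same sites in the MYB3R4 libraries would also give this. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, parted as many as 5815 genes (5813 and 2 in the 2 directions), and the highest other parted 533, a split that set MYB3R4 replicate 2, the longest MYB3R4 list, with MYB3R1 replicates 1 and 2; with 10 splits no share under 0.05 can be had. A difference between the 2 proteins in their genes remains among the open explanations and was not tested apart from these.

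Peaks crowded on chromosome 2 from 3.2 to 3.7 Mb, with 132, 12 and 156 in the MYB3R4, 56 and 41 in the MYB3R4mNES and 34, 2 and 13 in the MYB3R1 replicates. Reads of mitochondrial DNA placed on chromosome 2, whose pericentromere is known to carry a large mitochondrial insertion, are a candidate explanation: over the 8 libraries the number of peaks there rose with the number on the mitochondrial genome (Spearman's rho 0.98, permutation p = 3.97e-04; Pearson's r 0.95, permutation p = 9.92e-05, and 0.91 without the 2 libraries farthest from the median). No biological explanation was tested.

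In the list of the library labelled MYB3R4mNES replicate 1, the peak names carry the short name of MYB3R4 replicate 3. The same reads called under both labels are argued against, since 1.76% of its summits lie at the position of a MYB3R4 replicate 3 summit. A MYB3R4 library under the MYB3R4mNES label cannot be told apart from a correct label with a wrong name inside the file: with equal list lengths its overlap with MYB3R4 replicate 3 minus that with MYB3R4mNES replicate 2 was -2.20 percentage points, and libraries of both forms overlap too much for this to decide. Each statement on MYB3R4mNES rests on this library and 1 other. The peak at OLEO1 was the highest of MYB3R4 replicate 3 (fold enrichment 16.4) and of MYB3R4mNES replicate 2 (16.7). It was lower in MYB3R4mNES replicate 1, and OLEO1 was bound in 1 MYB3R4 library only. This 1 locus cannot decide on the labels. An exchange of labels was not tested and would put MYB3R4 replicate 3 in doubt as well.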

How the results depend on the processing

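The nearest gene end, the lists without dense windows, equal lengths combined with these, and the ribosomal list without resistance genes were chosen only after the results were seen. A test or odds ratio was taken as kept if its direction and side of the threshold stayed. Counts were taken as kept within 1.5 times, and replicate overlaps within their spread. Permutation tests over libraries cannot pass the threshold, so for them only the direction could change. Over 2493 values from 25 settings, results of a comparison were kept in 370, moved in 37 and reversed in 6. Of values for single lists and genes 1847 were kept, 16 lost a call, 216 moved (32 higher, 184 lower) and 1 reversed. Of the 1847, 1153 were numbers of libraries in which a named gene was bound. The G2/M list stayed enriched among targets in every setting, with odds ratios over settings that keep all libraries of 8.94 to 132 (MYB3R1), 6.20 to 40.0 (MYB3R4) and 29.3 to 70.5 (MYB3R4mNES). The cause was not tested for the following changes, except that shorter lists and stricter or looser rules call fewer or more genes by construction. The genes bound in 3 MYB3R1 and 0 MYB3R4 libraries (5813) numbered 2838 with a -log10 q of at least 10, 125 with equal list lengths, 3690 with the nearest gene end, 61 with equal lengths and no dense windows, and 5813 to 9519 with a library left out (9519 without MYB3R1 replicate 3). Those genes bound in 3 MYB3R4 and 0 MYB3R1 libraries (2) numbered 0 with a -log10 q of at least 10, with a 500 bp window or without dense windows, 12 with equal lengths, 19 with equal lengths and no dense windows, 5 with 2000 bp, 69 with any part of the peak, 1 with the nearest gene end, and 2 to 45 with a library left out (45 without MYB3R4 replicate 2, 4 without MYB3R1 replicate 1). The target genes of MYB3R1 (12283) numbered 6880 at -log10 q of 10, 319 at equal length, 194 at equal length without dense windows, 7383 in every library, 18465 in 1 or more, and 7472 (without replicate 2) to 12283 with a library left out (7933 without replicate 1). The target genes of MYB3R4 (385) numbered 189, 181, 143, 182 and 2646 in the same settings, 252 with 500 bp, and 237 (without replicate 2) to 385 (253 without replicate 1). The target genes of MYB3R4mNES numbered 70 at -log10 q of 10, 254 in 1 library or more, and 119 to 205 (without replicate 1, where 1 library is left). The lists enriched among targets of MYB3R1 (7) were 3 at equal length, 7 without dense windows and 2 with both, where lists also shrink from 227 to 141 peaks, and the lists enriched among targets of MYB3R4 (1) were 5 with 1 library or more. Of 44 ribosomal protein genes among targets of MYB3R1, 0 were left at equal length (odds ratio 0.952 by the correction for an empty cell, 0 without it). The difference planned as percent of summits in promoters, MYB3R4 against MYB3R4mNES, which counts windows at both gene ends (0.123), was 15.7 at -log10 q of 10, 11.2 at equal length, -0.865 with 500 bp, -7.77 without dense windows, -2.33 with replicate number as a block, and -8.09 (without MYB3R4 replicate 2) to 10.8 (without MYB3R4 replicate 1) with a library left out, with an exact permutation p of 0.20 or more in each. The replicate overlap, MYB3R4mNES, became 82.8% at -log10 q of 10, and the replicate overlap, MYB3R4 (45.6%), ran from 25.1% (reciprocal overlap) to 71.5% (equal length, no dense windows). No sign was seen that the numbers pair the samples. Deviations of MYB3R1 and MYB3R4 libraries with the same number from their group correlated at -0.08, -0.05 and 0.03 across genes. Those with unlike numbers correlated at -0.08 to 0.09. For MYB3R4 and MYB3R4mNES the values were 0.05 with the same number and -0.05 with unlike numbers, for replicates 1 and 2. Such small values do not exclude a shared batch. The replicate block gave 64.4 points for percent of G2/M list bound, MYB3R1 against MYB3R4 (exact permutation p = 0.25). Results on the mitosis-specific activator motif were not run. Depth is unknown; it may limit each list's length and so the counts of bound genes, which no value here tests.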

Other observations

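The gene families, the tRNA genes and the comparison of ranks over all bound genes below were chosen only after the data were seen; the test of the ranks of G2/M genes was fixed before its result. Among 233 families of genes with a common symbol, each with 8 members or more, tested on targets outside the dense windows, arabinogalactan proteins, glycoproteins of the cell surface, were the 1 family enriched among MYB3R4 targets, with 5 of 30 members (AGP1, AGP4, AGP15, AGP17 and AGP18; odds ratio 16.9, adjusted p = 0.00597 by Fisher's exact test). AGP1 and AGP15 were also MYB3R4mNES targets, where no family passed the test. Among MYB3R1 targets, 6 families were enriched and 8 depleted. All 9 beta-tubulin genes (TUB, odds ratio 23.5 with a correction for an empty cell, adjusted exact p = 0.0209) and 11 of 12 cytokinin response factors (CRF, odds ratio 13.6, adjusted exact p = 0.0359) were bound. Bound less often were low-molecular-weight cysteine-rich peptides (LCR, 7 of 80, odds ratio 0.118, adjusted exact p = 5.84e-10), cytochromes P450 (CYP, 60 of 229, odds ratio 0.436, adjusted exact p = 7.95e-07) and MYB genes (31 of 120, odds ratio 0.429, adjusted exact p = 0.00218).

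Of 625 tRNA genes, 137, 269 and 85 lay within 200 bp of a summit in MYB3R1 replicates 1, 2 and 3, against 28.8, 47.0 and 17.5 for random positions. In the MYB3R4 replicates the counts were 2, 12 and 8, against 1.3, 6.90 and 1.15, and in the MYB3R4mNES replicates 1 and 2, against 0.650 and 0.600. At OLEO1 (AT4G25140), an oleosin gene of seeds, fold enrichment was 16.4 in MYB3R4 replicate 3 and 16.7 in MYB3R4mNES replicate 2, the highest in both lists, 4.35 in MYB3R4mNES replicate 1, 2.56, 3.91 and 4.73 in the MYB3R1 replicates, and no peak was called in MYB3R4 replicates 1 and 2. Whether a transgene carried a copy of this promoter, whose reads would be placed here, was not tested, so that these values may not show binding at the gene itself. Given only to the nearest gene end, these peaks leave OLEO1 bound in 0 libraries.

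A hypothesis was that MYB3R4 targets among the G2/M genes are those with the strongest MYB3R1 peaks. The 16 MYB3R4 targets had a median percentile of MYB3R1 fold enrichment of 99.5 and the 39 other G2/M genes bound by MYB3R1 one of 96.5, a difference of 2.99 (permutation p = 2.00e-05, the smallest these permutations can give). The relation is not particular to this list, as the percentile was 97.6 for all 339 MYB3R4 targets bound by MYB3R1 and 47.5 for its 18126 other bound genes. It may reflect shared sites, of which libraries with weaker enrichment show only the strongest, or the stronger signal of accessible promoters. These data do not separate them.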
